A study of Canis lupus familiaris with 42 samples.

How the data were processed

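Transcript levels were measured in canine hemangiosarcoma, a malignant tumour of the cells that line blood vessels, on 42 microarrays. Per the labels' protocols, 12 arrays held RNA from monolayer cultures, 6 from cells cultured without serum or attachment (spheres) and 24 from snap-frozen tumour tissue. Per the labels' protocols, total RNA was extracted with the TriPure reagent followed by RNeasy columns, samples were accepted with an absorbance ratio of 1.95 to 2.1 and an RNA integrity number above 6.1, and 500 ng of RNA were amplified and labelled with the single dye Cy3.

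The deposited scanner files hold the intensity of each spot on a linear scale, and per the file headers they were written by Agilent Feature Extraction 10.5.1.1 in a single-colour protocol. The processed intensity used here was already background-corrected by the authors' scanner software and was not scaled between arrays, per the file headers. The authors' deposited series table holds intensity values on a linear scale, and how they were made is not given in the sources used here. Set against the scanner files, each of its columns kept the spot order of that array's median pixel intensity (Spearman 1.0) and all columns had nearly the same median (147.02 to 147.9), the pattern that quantile normalization of intensities without background subtraction gives. Its correlation with the processed intensity ran from 0.844 to 0.971. It was used only as an alternative.

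Each array held 45220 spots, of which 43803 were not controls. Control spots were left out, as were spots that the scanner software marked as non-uniform or as population outliers (at most 18 on an array), while saturated spots would have been kept (0 were saturated). The values were log2 of the processed intensity minus the array's 75th percentile, so a level is relative to that percentile of the same array. Spots of the same probe were averaged, giving 43603 probes. The files name probes by accession. RefSeq transcript accessions were named through a table of the UU_Cfam_GSD_1.0 assembly, which matched 831 of 892 and left 61 unmatched, so 1313 probes carried 1 of 832 symbols and 42290 probes had none. No coordinates are given because the array design names no genome build. Probes with the same symbol or accession formed a target (35908 targets), represented by the probe with the highest mean over the arrays in the fit, and the other probes of a gene named in the report are given where they differed in sign or by more than 1 log2 unit from a difference printed there.

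Targets were kept where the probe was well above background, by the scanner software's test, on at least as many arrays as the smaller group had. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment, and an adjusted p under 0.05 counted as past the threshold. In the comparisons with monolayers the code in the sample title was a random block (duplicateCorrelation, statmod 1.5.0), because some codes occur on several arrays. The code SH was split into separate cases, since it marks a German Shepherd spleen monolayer and a Golden Retriever heart tissue. The organs were compared in a fit over all 24 tissues by organ, and the breeds in a fit with organ as a covariate. Where a gene was not well above background on any array of the dimmer group, the fold is a bound: the bright group's mean over the mean, per array, of the higher of the lowest signal among probes well above background and the dim probe's own signal.

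Gene lists, 27 in number, were written before the data were examined, as were the comparisons, their tests, the rule for named genes and most alternatives. Lists with at least 3 tested members were tested with limma's camera on moderated statistics with a preset correlation of 0.01, against the tested targets that had symbols. Each list test was also run with a correlation estimated from the residuals, which is given for the lists that passed. The basement membrane and cholesterol biosynthesis lists had 0 members on the array under a symbol. Named genes were the 10 largest and 10 smallest differences with a symbol past the threshold, for spheres only among genes with the same sign in all 4 lines grown both ways, plus up to 4 members past the threshold of each list and a fixed set of well-known members. Values of 2 genes are not reported here. Correlations between list scores (the mean of centred log2 values) across tissues have permutation p-values from 100000 permutations, adjusted over 10 pairs. Coherence is the mean correlation between the members of a list, set against 10000 random lists of the same size drawn from the 60 genes nearest in mean level to each member.

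The spread between samples was checked before values were pooled. No 2 arrays of the same group held identical values, and repeat arrays of a line correlated at 0.926 to 0.979. Pairs of different codes reached 0.982 among monolayers (median 0.928), 0.949 among spheres (median 0.889) and 0.970 among tissues (median 0.925), so the ranges overlapped. The 5 pairs of arrays that share a group and a line code entered as separate arrays with the code as a block. The labels do not say whether repeat arrays of a code came from separate cultures, so p-values measure the spread between these samples, which may in part be technical. For the sphere comparison the lines pair the samples, since the same line codes occur in both culture forms. The deviations from the group means correlated at 0.44 to 0.61 between the SB spheres and the SB monolayer, at 0.21 and 0.46 for JHE, at 0.32 for EFB and at -0.13 and -0.11 for FH, with a mean of 0.29 against -0.04 for pairs of different lines.

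Recovery was tested on simulated data drawn from the real means and spreads, with 200 targets changed by known amounts. Among 16942 targets the sphere comparison recovered 40% of changes of 1 log2 unit and 92% of changes of 4 units, and among 17790 targets the tissue comparison recovered 68% and 100%. The heart comparison recovered 22% and 76% of changes of 1 and 2 units among 18203 targets, the liver comparison 14% and 70% among 19072, and the breed comparison 26% and 70% among 18203. The test of whether lines respond alike recovered 2% of changes of 2 units and 64% of changes of 4 units among 15769 targets. Of all calls in these simulations, 0.98% to 7.62% were false.

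Precision is limited by the number of arrays in each group. The arrays were scanned on 2 days: all monolayers, all spheres and 10 tissues on the first, and 14 tissues on the second. They lay on 12 slides, numbered here from 1 to 12. Alternatives covered quantile normalization, normexp background correction followed by quantile normalization, the series table, the filter on dim probes, the probe per gene, the blocks by line, code or slide, scan day and the samples left out. The mean pixel intensity that the normexp alternative was planned with is not used here, because the files analysed hold the median pixel intensity, which took its place. Figures were drawn with matplotlib 3.10.9.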

Results

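Canine hemangiosarcoma was profiled in 3 forms: 12 arrays of monolayer cultures, 6 arrays of sphere cultures and 24 arrays of snap-frozen tumour tissue. The monolayers carried 10 line codes and the spheres 4, and the 4 lines with spheres (EFB, FH, JHE and SB) were also grown as monolayers. Line SB had 3 sphere arrays, and lines FH and JHE had 2 monolayer arrays each. By label the monolayer arrays came from the spleen (6), heart (2), and liver, lung, brain and cutaneous sites (1 each). Of these, 8 came from Golden Retrievers and 4 from other breeds, a dog labelled GR Mix among them. The sphere arrays were labelled skin (3), and brain, heart and spleen (1 each), 3 of them from Golden Retrievers and 3 from a German Shepherd. The tissues came from the spleen (11), heart (7), liver (5) and lung (1), 17 of them from Golden Retrievers and 7 from other breeds. On each array 38.3% to 57.7% of the probes were well above background, and the 75th percentile of the processed intensity ran from 92.5 to 494 (median 249). Genes with a symbol made up 832 of the 35908 targets, so counts cover all targets while gene groups rest on the genes with symbols. All differences are in log2 units with the standard error of the limma fit. The series text speaks of molecular subtypes, which the sample labels do not assign, and no comparison of subtypes was made.

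Sphere cultures, a form used to enrich for tumour cells that can renew themselves, were compared with monolayers. ACKR3, a scavenger receptor for the chemokine CXCL12, was higher in spheres (log2 difference 6.92, 95% interval 4.83 to 9.01, n = 6 and 12 arrays, adjusted p = 0.000713). It was higher in each of the 4 lines grown both ways, by 3.51 in EFB, while the FH and JHE monolayers were not well above background. The probe was well above background on all 6 sphere arrays and on 5 of 12 monolayer arrays. GUCY1A1, a subunit of the nitric oxide receptor, was higher (5.04 ± 0.57, adjusted p = 7.05e-05), with all 6 sphere arrays and 2 of 12 monolayer arrays well above background. BIRC3, an inhibitor of apoptosis, was lower in spheres (-3.25 ± 0.48, adjusted p = 0.000891), with 2 of 6 sphere arrays well above background. HMGA1, an architectural chromatin protein, fell in all 4 lines (-2.76 ± 0.35, adjusted p = 0.000194). MET, the receptor of hepatocyte growth factor, was not well above background on any sphere array and was at least 7.14-fold lower than in monolayers with its brightest probe (adjusted p = 0.0015), while its other probe differed by -2.17.

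The interferon response genes rose together in spheres. All 3 tested members passed over all genes, and all 3 also adjusted over the list alone. MX1, an antiviral GTPase, was higher (5.44 ± 1.17, adjusted p = 0.00668, well above background on 5 of 6 sphere and 5 of 12 monolayer arrays), OAS1 was 1.99 ± 0.54 higher and OAS2 1.85 ± 0.55 higher. The list median was 1.99 (adjusted p = 0.0188, and adjusted p = 0.314 with an estimated correlation). By line, the median of these genes was 3.49 in EFB, 2.91 in FH, 2.79 in SB and 0.07 in JHE. Of 9 inflammatory cytokine and chemokine genes tested, 2 were higher, and the same number adjusted over the list alone. These were the monocyte attractants CCL8 (4.28 ± 0.81, adjusted p = 0.0033, well above background on 7 of 12 monolayer arrays) and CCL2 (16.7-fold, 4.06 ± 0.76, adjusted p = 0.00319). The other 7 did not pass, among them CXCL8 (adjusted p = 0.331) and IL6 (2.53 ± 1.36, adjusted p = 0.203, well above background on 3 of 6 and 4 of 12 arrays). The list median was 2.36 (adjusted p = 0.0188, and adjusted p = 0.314 with an estimated correlation). With slide as a fixed block these medians were 0.79 for interferon and 1.47 for inflammatory genes. On the 2 slides that held both culture forms the interferon median was 0.86 and 1.02, and the inflammatory median was -0.59 and 3.43. The first of these slides set the JHE sphere against DD and GM monolayers, the second the FH sphere against JHE and FH monolayers. These values therefore mostly compare different lines.

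Other genes lower in spheres were the cyclin CCNB3, at -2.95 ± 0.75 (adjusted p = 0.0156, well above background on 3 of 6 sphere arrays), and BIRC5, the only member of the proliferation list with a symbol on the array, at -2.73 ± 0.55 (adjusted p = 0.00464). The transcription factor MYC differed by -2.10 ± 0.49 (adjusted p = 0.00991). The growth factors KITLG (-3.16) and FGF5 (-3.03), the progesterone receptor PGR (-2.81), CUBN (-3.10) and OPTC (-2.95) were also among the 10 largest decreases. Of the 6 sphere arrays KITLG was well above background on 5, FGF5 and PGR on 3, and CUBN and OPTC on 2, and OPTC was so on 7 of 12 monolayer arrays. Beside ACKR3, GUCY1A1, MX1, CCL8, CCL2 and OAS1, the 10 largest increases held MMP9, a matrix protease (3.88 ± 0.97, well above background on 1 of 12 monolayer arrays), PTGDS (3.63 ± 0.93), SULF2 (2.23 ± 0.50, on 4 of 12) and the anticoagulant receptor THBD (1.65 ± 0.33).

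Endothelial identity genes did not pass in spheres. KDR, a receptor of vascular endothelial growth factor, differed by 0.82 ± 0.55 (adjusted p = 0.31, well above background on 4 of 6 and 4 of 12 arrays) and VWF, a clotting protein of endothelial cells, by 0.66 ± 0.26 (adjusted p = 0.0899). Of the 3 tested, 0 passed over all genes and 2 adjusted over the list alone. For this list limma's test gave an adjusted p of 0.128, with 5486 targets of the comparison at an unadjusted p under 0.05. Angiogenic genes had 1 lower of 4 tested, over all genes and adjusted over the list alone (ADM, a vasodilator peptide, -1.78 ± 0.38). Hypoxia genes had that same gene lower of 3 tested (list adjusted p = 0.128 each). Of 2 adipogenesis genes tested, CAV1, a caveolar coat protein, was lower (-1.58 ± 0.33), and adjusted over the list alone 1 was higher and 1 lower. None of the 6 fibroblast genes passed by limma (COL1A1 -0.04 ± 0.28, its other probes -0.09 to 0.20, list adjusted p = 0.336), nor any of 4 antigen presentation genes, of which 1 passed adjusted over the list alone (list adjusted p = 0.128). Among 3 immediate early genes MYC was lower, and the list median (0.53) lay on the other side of 0 from the mean and the test (-0.10, adjusted p = 0.988).

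In all, 2525 of 16953 targets (14.9%) passed between spheres and monolayers, 1070 higher and 1455 lower in spheres, and 1271 differed at least 2-fold. Of 457 targets with a symbol, 30 were higher and 44 lower. The share of higher calls was 42.4%, against 57.1% of 2582 calls with the percentile taken over the probes well above background on every array. Spheres and monolayers lay on 8 slides, of which only 2 held both forms (2 spheres and 4 monolayers). With slide as a fixed block 9 targets passed, 7 of them shared with the 2525. With slide as a random block, which took the place of the block by line, 751 passed, against 1625 with neither block. The 74 named genes past the threshold had a median difference in their direction of 0.87 and 0.85 within these slides against 1.27 over all arrays. These genes were chosen in a fit with the same arrays, and the slides mostly set a sphere against monolayers of other lines. Without line EFB 993 targets passed, without JHE 1224, without SB 928 and without FH 2065. With line as a fixed replicate block, which uses the 12 arrays of the 4 lines grown both ways, 1549 passed, and over all 18 arrays without the block by line 1625.

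**Figure D1:**
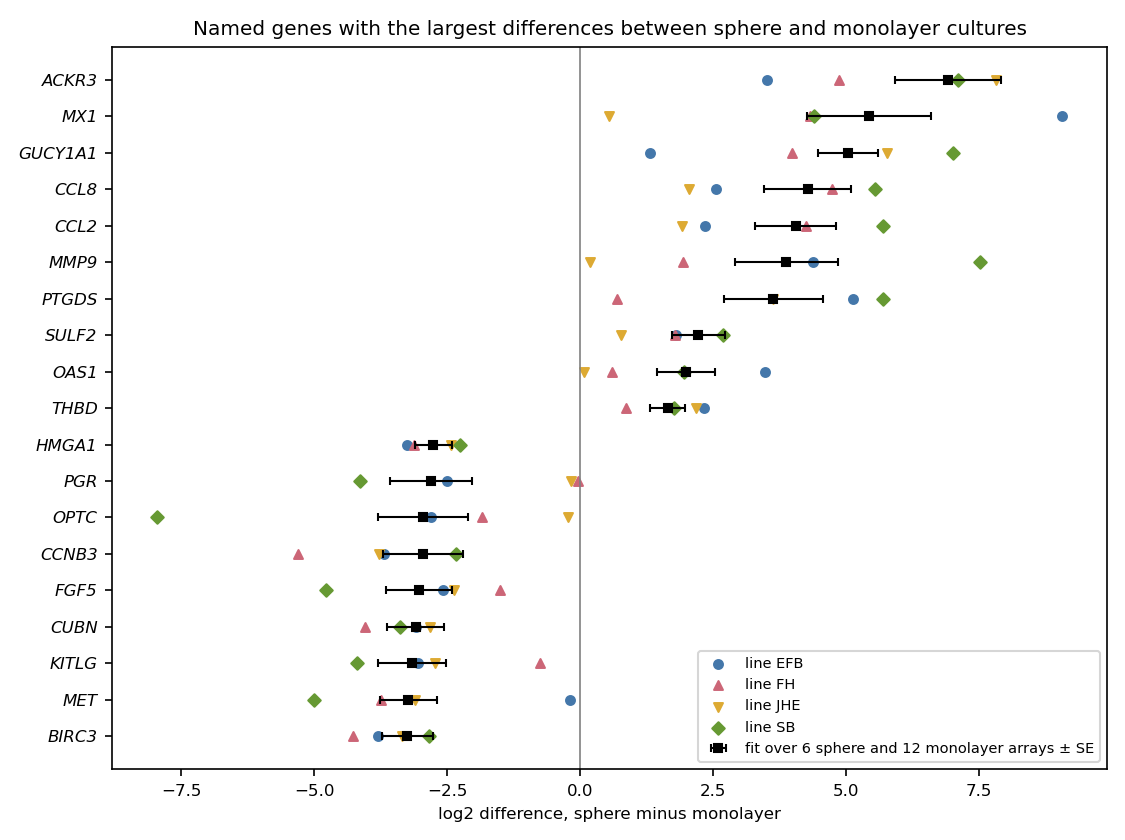
Log2 difference, sphere minus monolayer (x axis), for the 10 named genes with the largest increases and 9 with large decreases (y axis). Black squares with bars are the fit over 6 sphere and 12 monolayer arrays ± SE, coloured points are the differences within lines EFB, FH, JHE and SB, as measured also where arrays were not well above background. Every gene lies on the same side of 0 in all 4 lines, as the rule for naming required, with PGR in FH (-0.05) and OAS1 in JHE (0.07) nearest to 0.

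The sphere response of line SB was then set against the mean response of EFB, FH and JHE. SB is labelled German Shepherd and cutaneous or skin, while the others are labelled Golden Retriever and other organs. Line, breed and organ therefore cannot be told apart here. The p-values of this comparison rest on repeat arrays of the same lines (4 residual degrees of freedom, with 1 monolayer array of SB) and leave out the spread between lines, so they do not show that SB differs from lines in general. For 7 inflammatory cytokine genes the median difference was 2.62 (adjusted p = 0.00327, and adjusted p = 0.123 with an estimated correlation), with median sphere responses of 4.53 in SB, 4.25 in FH, 2.56 in EFB and -1.35 in JHE, so SB stood close to FH and far from JHE. The 6 fibroblast and fibrillar matrix genes had a median difference of 0.90 (adjusted p = 0.0193, and adjusted p = 0.341 with an estimated correlation), from 1.37 in SB, 0.84 in FH, 0.12 in JHE and 0.04 in EFB. KDR (1.74 ± 1.17, adjusted p = 0.843), VEGFA (1.68 ± 1.17, adjusted p = 0.847, its other probe -1.41) and CXCL8 (1.15 ± 2.32, adjusted p = 0.953) did not pass. Of 15774 targets 0 passed by limma, with 1128 at an unadjusted p under 0.05, and 3 passed without line JHE. This test could find few differences below 4 log2 units, as 64% of simulated differences of that size and 2% of those of 2 units were recovered among 15769 targets.

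Tumour tissue was compared with the monolayers to show what the cultured cells lack of the tumour, and what they gain. Genes of antigen presentation and macrophages were far higher in tissue. The class II molecule DLA-DRA differed by 10.08 ± 0.51 (n = 24 and 12 arrays, adjusted p = 4.96e-19, its other probe 8.49) and DLA-DQB1 by 9.68 ± 0.46 (its other probes 8.08 to 9.39), with 3 and 5 of 12 monolayer arrays well above background. The costimulatory molecule CD86, the scavenger receptor CD163 and the Fc receptor FCGR1A were well above background on all 24 tissue arrays and on no monolayer array, and were at least 244-fold, 213-fold and 104-fold higher (the other probe of CD163 differed by 7.77). Endothelial genes were also higher, KDR by 7.49 ± 0.44 (adjusted p = 5.76e-17, well above background on 4 of 12 monolayer arrays) and VWF 36.8-fold (5.20 ± 0.33, adjusted p = 2.92e-16). FGF5 was not well above background on any tissue array and was at least 11.4-fold lower than in monolayers, and HMGA1 was lower by 4.19 units (-4.19 ± 0.30, adjusted p = 1.12e-14).

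**Figure D2:**
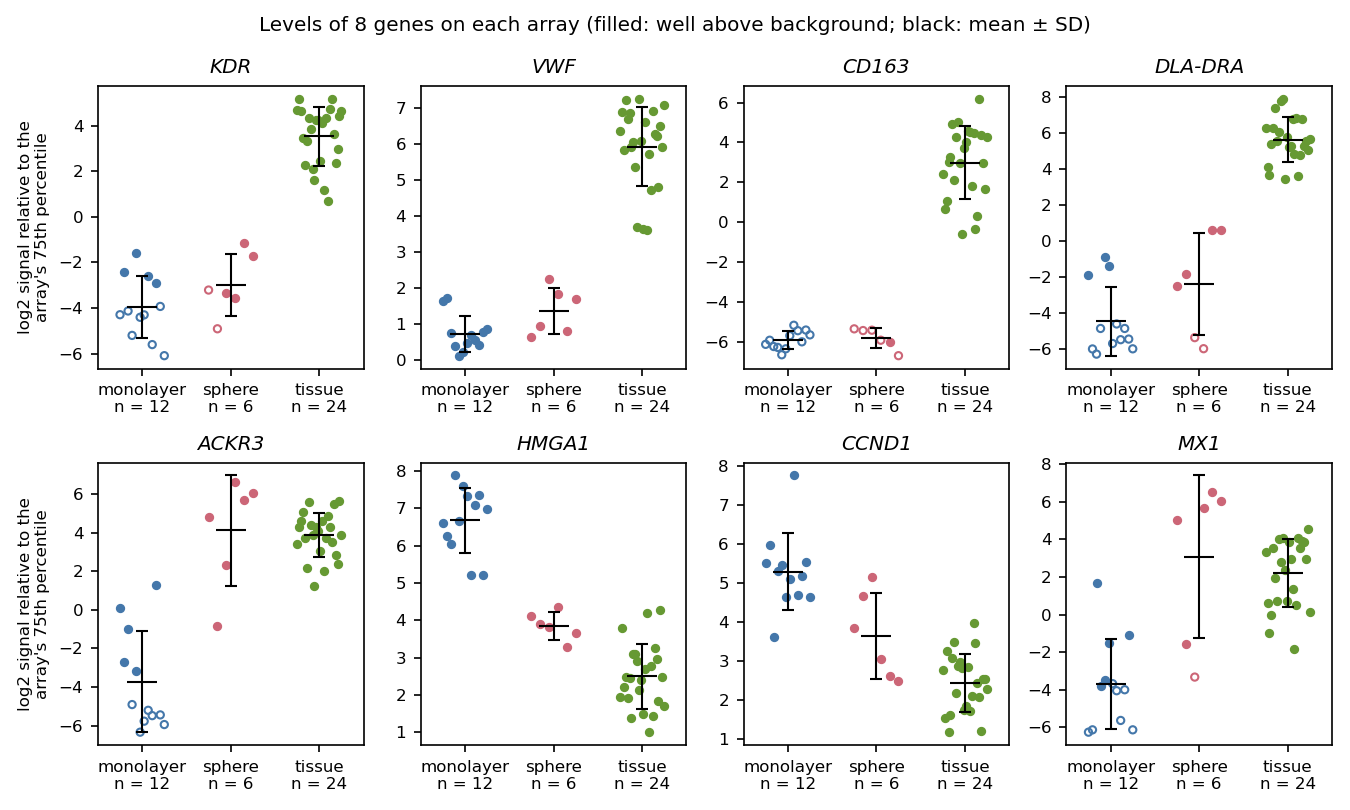
Level of 8 genes (y axis, log2 intensity relative to the array's 75th percentile) on each array of monolayer (n = 12), sphere (n = 6) and tissue (n = 24). Filled points are arrays with the probe well above background, open points are not, and black bars are mean ± SD, which for KDR are -3.96 ± 1.36 in monolayers, -2.99 ± 1.35 in spheres and 3.53 ± 1.28 in tissue.

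Of the 15 lists tested, 4 passed as a group. All 5 macrophage and monocyte genes were higher in tissue, over all genes and adjusted over the list alone (median 7.92, adjusted p = 0.000419, and adjusted p = 0.0956 with an estimated correlation), CYBB, a subunit of the phagocyte oxidase, by at least 123-fold. All 5 antigen presentation genes were higher, and 5 adjusted over the list alone (median 6.38, adjusted p = 0.00635, and adjusted p = 0.0956 with an estimated correlation), among them the protease CTSS (7.54 ± 0.49) and the proteasome subunit PSMB8 (6.38 ± 0.42), well above background on 3 and 2 of 12 monolayer arrays. All 3 endothelial identity genes were higher, and 3 adjusted over the list alone (median 5.20, adjusted p = 0.0313, and adjusted p = 0.0956 with an estimated correlation), though NOS3 differed by 1.36 with the brightest probe and by 3.49 and 5.34 with its other probes. Of 13 inflammatory cytokine genes 12 were higher and 1 lower, in the same numbers adjusted over the list alone (median 3.33, adjusted p = 0.0414, adjusted p = 0.0553 after quantile normalization, and adjusted p = 0.211 with an estimated correlation). CCL4 was at least 28.5-fold higher and SELE higher by at least 4.32 log2 units with its brightest probe (its other probe differed by 3.24), VCAM1 differed by 4.92 ± 0.75 and IL6 by 4.16 ± 0.82 (on 5 and 4 of 12 monolayer arrays well above background). PTGS2, the inducible cyclooxygenase, differed by -3.21 ± 0.74. Within the 5 slides that held both tissue and monolayers the medians of these lists were above 0 on every slide. They were 6.88 to 9.26 for macrophages, 4.51 to 9.10 for antigen presentation, 3.65 to 5.61 for endothelial identity and 2.96 to 5.93 for inflammatory genes. With slide as a fixed block they were 7.75, 6.29, 4.95 and 4.13, and among the arrays of the first scan day 8.19, 6.45, 5.36 and 3.74.

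The other 11 lists did not pass as groups in limma's test, though most of their members did. All 3 tested blood and endothelial progenitor markers were higher (CD34 4.17 ± 0.42, KIT at least 19.9-fold; list adjusted p = 0.0809, and 0.0171 with all targets as background), as were all 3 neutrophil and mast cell genes (MMP9 5.86 ± 0.65, CAMP 6.83 ± 0.92; 0.105, and 0.0313 with all targets as background), all 3 interferon genes (MX1 5.90 ± 0.69, its other probe 4.07; 0.286) and all 3 hepatocyte genes (SERPINA1 at least 258-fold; 0.2), whose levels were highest in the 4 tumours NP, JLI, SAS and SJ (APOH was well above background on 13 of 24 tissue arrays). All 3 hypoxia and glycolysis genes were lower (GAPDH -1.06 ± 0.17, VEGFA -1.46 ± 0.24 with its other probe at -2.52, ADM -1.51 ± 0.44; 0.105). Of 5 angiogenic genes 2 were higher (ANGPT2, a vessel-destabilising ligand, at least 55.5-fold, and CXCL12 3.46 ± 0.49) and 3 lower (list adjusted p = 0.91, with a negative median of -1.46 and a positive mean of 1.08). Of 6 fibroblast genes 1 was higher (COL6A3 1.95 ± 0.62) and 4 lower, with DCN at -2.67 ± 0.71, COL1A2 at -2.18 ± 0.43 and BGN at -1.54 ± 0.38 (0.215). COL1A1 itself did not pass with its brightest probe (-1.09 ± 0.54, adjusted p = 0.0724), while its other probes gave -2.64 to -2.18. Of 3 adipogenesis genes 2 were higher, led by PPARG, a regulator of fat cells (6.24 ± 0.37; list 0.323), of 3 immediate early genes 2 (NR4A1 1.90 ± 0.50; 0.623), of 3 erythroid genes 2 (0.608), and of 3 platelet genes 2 were higher and 1 lower (GP1BA 4.75 ± 0.50, ITGB3 -2.05 ± 0.40; 0.63). Of the genes named here, those well above background on only some of the 12 monolayer arrays were ITGB3 (11), CD34 (10), CAMP, MX1 and NR4A1 (5 each), CXCL12 (4), COL6A3 (6), PPARG (3), and MMP9 and GP1BA (1 each), and ITGB3 was so on 8 of 24 tissue arrays. For each of these lists the counts adjusted over the list alone were the same.

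Among single genes the 10 largest increases also held SELENOP, a selenium transport protein (9.38 ± 0.62, its other probes 7.39 to 8.94), HLA-DRB1 (8.83 ± 0.59, its other probes 5.89 to 9.08) and ACKR3 (7.58 ± 0.60), well above background on 7, 10 and 5 of 12 monolayer arrays. The 10 largest decreases held PGR (-4.70 ± 0.46), ARSJ (-4.03 ± 0.34), the adenosine receptor ADORA2B (-3.88 ± 0.44), PDPN, a membrane glycoprotein of lymphatic endothelium (-3.52 ± 0.70), the growth factor FGF7 (-3.01 ± 0.66), BHLHE41 (-2.98 ± 0.38) and the cyclin CCND1 (-2.83 ± 0.29), beside FGF5, HMGA1 and PTGS2. Of the 24 tissue arrays PGR was well above background on 6, ARSJ on 3, ADORA2B on 15, PDPN on 13, FGF7 on 12 and PTGS2 on 20. In all, 12353 of 17835 targets (69.3%) passed, 5653 higher and 6700 lower in tissue, and 6973 differed at least 2-fold. Of 530 targets with a symbol, 228 were higher and 172 lower. The median difference of all targets was -0.14. It was 0.27 with the percentile taken over the probes well above background on every array, where 66.8% of 11444 calls were higher against 45.8% here. With slide as a fixed block 8071 targets passed, 7774 of them shared. With the 4 codes that had both a tissue and a monolayer as a fixed replicate block (9 arrays, SH left out) 4409 passed.

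Heart, liver and spleen tumours were compared to ask whether the organ marks the tumour's transcripts. In heart tumours the 3 cardiomyocyte genes tested were shifted up as a group against spleen tumours (median 1.79, adjusted p = 0.0243, and adjusted p = 0.342 with an estimated correlation), with the troponin TNNT2 at 2.91 (95% interval 0.97 to 4.85) and PLN, a regulator of the cardiac calcium pump, at 1.79 (0.01 to 3.58), in 7 heart and 11 spleen tumours. The 6 fibroblast and fibrillar matrix genes were shifted up (median 0.94, adjusted p = 0.0137, and adjusted p = 0.342 with an estimated correlation), led by DCN at 1.89 (0.24 to 3.54). The 4 neutrophil and mast cell genes were shifted down (median -1.43, adjusted p = 0.0282, and adjusted p = 0.342 with an estimated correlation), with CAMP, an antimicrobial peptide of neutrophils, at -3.09 (-6.03 to -0.15) and MS4A2, a mast cell receptor subunit, at -1.90 (-3.24 to -0.56). Over all genes none of these members passed, and adjusted over the list alone 1 cardiomyocyte gene was higher, 1 neutrophil or mast cell gene was lower and 0 fibroblast genes passed by limma. On the first scan day (4 heart and 3 spleen tumours) the medians were 0.68 for cardiomyocyte, 1.13 for fibroblast and -0.87 for neutrophil and mast cell genes. On the second day (3 and 8) they were 2.67, 1.26 and -1.51. With slide as a fixed block they were 1.96, 0.78 and -1.05, and within the 5 slides that held both organs they ran from -1.54 to 5.23, from -0.96 to 1.74 and from -3.86 to 3.51.

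In liver tumours the 6 fibroblast and fibrillar matrix genes were shifted down against spleen tumours (median -1.39, adjusted p = 0.00596, and adjusted p = 0.767 with an estimated correlation; n = 5 and 11), with TIMP1, an inhibitor of matrix proteases, at -1.97 (95% interval -3.22 to -0.72) and COL1A1 at -1.79 (-3.47 to -0.11, its other probes -1.47 to -0.46). Over all genes 0 of the 6 passed by limma and adjusted over the list alone 1 was lower. This median was 0.10 among the 2 liver and 3 spleen tumours of the first scan day and -1.88 among the 3 and 8 of the second, -2.35 with slide as a fixed block, and -2.99 and -2.80 within the 2 slides that held both organs. The 4 hepatocyte genes had a median difference of 2.48 and did not pass as a group (adjusted p = 0.0914), with wide intervals such as -2.57 to 7.93 for APOH, a plasma protein made in the liver. Their mean level was 8.52 and 8.38 in the liver tumours NP and JLI, and 7.49 and 6.25 in the spleen tumours SAS and SJ. It was -1.72, -2.40 and -2.94 in the liver tumours AH, TCL and SAL. In all 20 tumours other than NP, JLI, SAS and SJ it lay between -3.69 and 0.59.

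**Figure D3:**
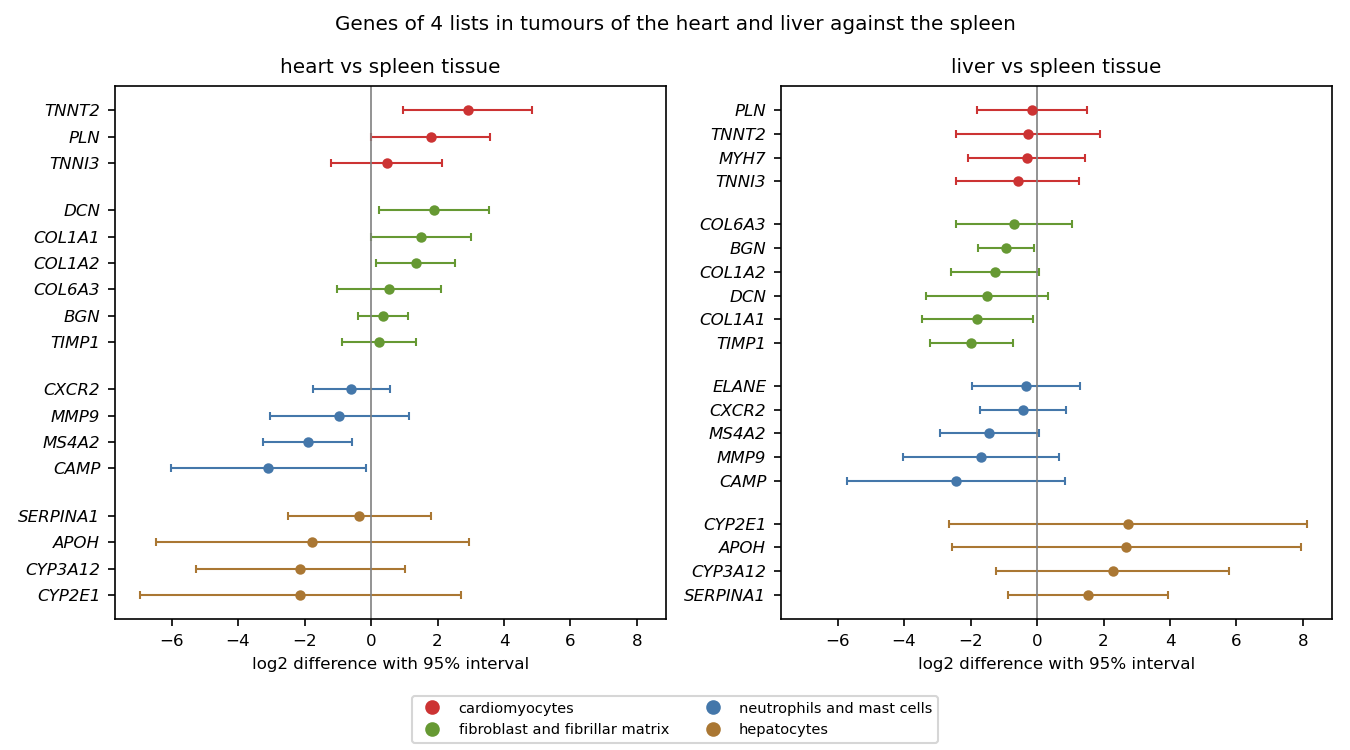
Log2 difference (x axis) with its 95% interval for each tested gene (y axis) of 4 lists, heart against spleen tumours (left, n = 7 and 11) and liver against spleen tumours (right, n = 5 and 11). TNNT2 lies at 2.91 in heart tumours with an interval above 0, and TIMP1 at -1.97 in liver tumours with an interval below 0.

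No single target passed between organs. Of 18242 targets 0 passed between heart and spleen by limma, with 803 at an unadjusted p under 0.05, and of 19113 targets 0 passed between liver and spleen, with 1168. KDR differed by 0.37 ± 0.62 between heart and spleen and by 0.05 ± 0.70 between liver and spleen, and VWF by 0.50 ± 0.52 and -0.24 ± 0.58 (each short of the threshold). The median half-width of the 95% intervals was 0.63 for heart and 0.72 for liver. Of simulated differences of 1 log2 unit 22% were recovered for heart and 14% for liver, so most differences of that size would be missed. Without the liver tumour SAL 1 target, which has no gene symbol, passed between liver and spleen.

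Golden Retrievers, a breed with a high risk of this tumour, were compared with other breeds. The list nearest to the threshold was that of the 3 hypoxia and glycolysis genes, which did not pass (median -0.60, adjusted p = 0.0792; VEGFA -0.60, 95% interval -1.16 to -0.04; n = 17 and 7). IL6 differed by -2.15 (-4.01 to -0.30, adjusted p = 0.885) and CXCL8 by -1.28 (-2.81 to 0.25, adjusted p = 0.911). PPARG (0.57 ± 0.38, adjusted p = 0.914) and KDR (0.04 ± 0.61, adjusted p = 0.994) did not pass either. Of 18242 targets 0 passed by limma, with 1010 at an unadjusted p under 0.05, and no list passed. Over the list alone 1 hypoxia gene and 1 angiogenic gene were lower, which may be the same gene, since both lists hold VEGFA and ADM.

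Across the 24 tumours the list scores moved together in some pairs. Tumours with high endothelial scores (KDR, VWF and NOS3) had low T and NK cell scores (CD4, CD8A, CTLA4 and KLRD1). Pearson's r was -0.751 (permutation p = 4e-05, adjusted p = 0.0004) and Spearman's rho was -0.608 (permutation p = 0.00192, adjusted p = 0.0155). The relation was -0.634 without the 2 tumours farthest from the median endothelial score, -0.348 without the 4 tumours with the highest T and NK cell scores, which lie apart from the rest, -0.823 and -0.713 within the first and the second scan day, and -0.775 with the organ means removed. Endothelial scores rose with adipogenesis scores (PPARG, ADIPOQ, LEP and CAV1; r = 0.594, permutation p = 0.00183, adjusted p = 0.00915; rho = 0.581, permutation p = 0.0031, adjusted p = 0.0155; 0.458 without the 2 farthest and 0.337 without the 4 farthest; 0.437 and 0.702 within scan days). This pair did not pass with median scores (adjusted p = 0.0637) or in spleen tumours alone (adjusted p = 0.104). Macrophage scores rose with T and NK cell scores (Pearson's permutation p = 0.00837, adjusted p = 0.0279; rho = 0.46, permutation p = 0.0246, adjusted p = 0.0492; r = 0.487 without the 2 farthest; 0.375 without the 4 tumours with the highest T and NK cell scores; 0.557 and 0.522 within scan days; adjusted p = 0.128 in spleen tumours alone). Adipogenesis scores fell with T and NK cell scores (r = -0.498, permutation p = 0.0125, adjusted p = 0.0313; rho = -0.48, permutation p = 0.0187, adjusted p = 0.0492; -0.584 without the 2 farthest; -0.171 without the 4 tumours with the highest T and NK cell scores; -0.444 and -0.577 within scan days; adjusted p = 0.476 with median scores). These are 4 of 10 pairs, and the other 6 did not pass by Pearson's r (endothelial against macrophage scores r = -0.436, permutation p = 0.0333, adjusted p = 0.0666). That pair passed by Spearman's rho (-0.471, permutation p = 0.0208, adjusted p = 0.0492). Its rho did not pass after quantile normalization (permutation adjusted p = 0.0828) or with median scores (permutation adjusted p = 0.0554). The T and NK cell score also fell with the 75th percentile of the array's intensity (r = -0.442, permutation p = 0.0309), and the endothelial score had an r of 0.383 with it (permutation p = 0.066).

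**Figure D4:**
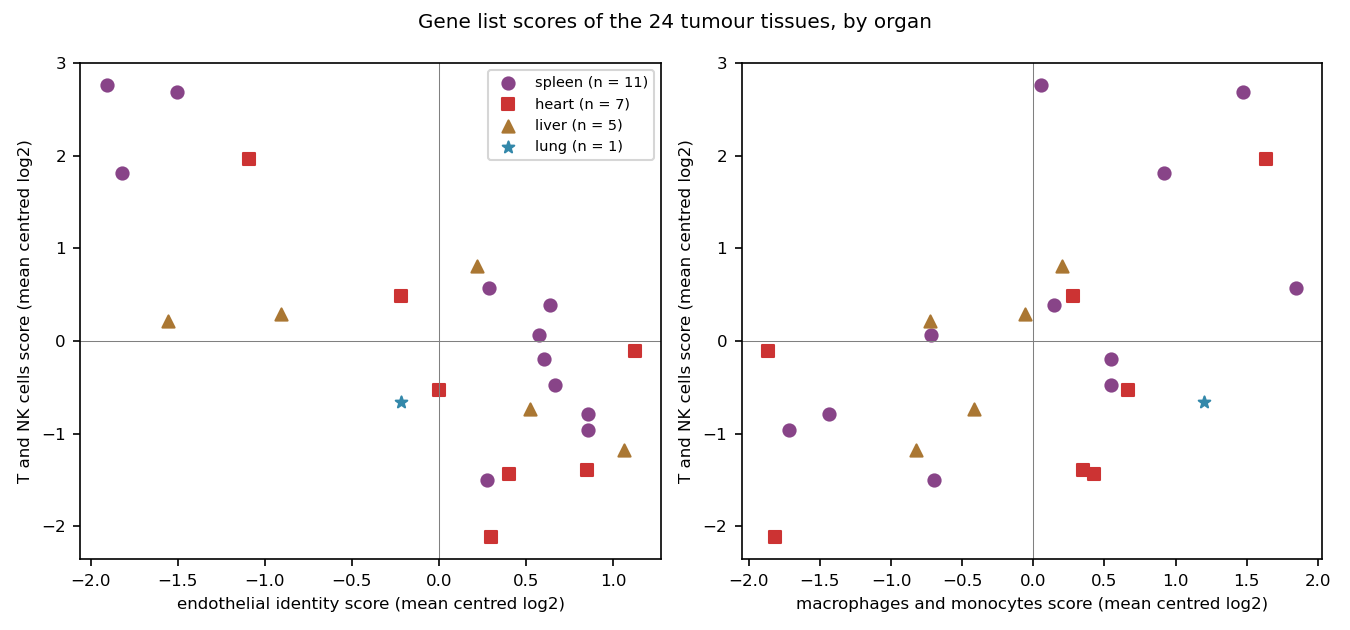
Scores (mean of centred log2 values of the list genes) of the 24 tumours, T and NK cells (y axis) against endothelial identity (left x axis) and against macrophages and monocytes (right x axis), with the organ as symbol. The left plot falls from upper left to lower right (r = -0.751), with 3 spleen tumours and 1 heart tumour at the upper left, and the right plot rises (rho = 0.46).

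Genes of a list varied together between tumours in 8 of 17 lists tested, each against random lists of the same size and level (adjusted p under 0.05). The mean correlation was 0.909 for hepatocyte genes, 0.688 for endothelial identity, 0.634 for macrophages, 0.582 for fibroblast and fibrillar matrix genes, 0.559 for antigen presentation, 0.425 for cardiomyocyte genes, 0.415 for neutrophil and mast cell genes and 0.129 for inflammatory cytokines. The adipogenesis genes did not vary together (-0.08, at the 27.9th percentile of random lists), so their score is not that of a common programme. The T and NK cell genes, whose score enters most of the related pairs, did not pass either (0.362, adjusted p = 0.0886 against random lists). Their score is thus not shown to be that of a common programme. With the organ means removed 5 lists passed.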

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

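Of the tests in this part, those of exchanged organ labels and of carry-over between arrays, the fits without the tumours SAS, SAL and SJ, the fits with slide as a random block, the interval of the slide ratio and the slide values over all targets past the threshold were chosen only after the results were seen.

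In spheres BIRC3 stood at -1.24 on the array SB1 and between -5.67 and -4.04 on the other 5 arrays, a gap of 0.632 of the range. It was the 1 sample apart among 67 groups of values tested, and chance alone sets about 1 group in 20 apart. The sphere response of line SB was larger than the mean of EFB, FH and JHE for the inflammatory cytokine genes, by a median of 2.62 over 7 genes (adjusted p = 0.00327, and adjusted p = 0.123 with an estimated correlation), though SB (4.53) lay close to FH (4.25) and JHE stood at -1.35. It was also larger for the fibroblast and fibrillar matrix genes, by a median of 0.90 over 6 genes (adjusted p = 0.0193, and adjusted p = 0.341 with an estimated correlation). Both p-values rest on repeat arrays and not on the spread between lines, so neither shows that SB responds more than other lines.

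Spheres and monolayers differed in 2525 targets, which only the real split reached, 1 of 100 splits of the same arrays. The highest other split gave 239, and the 16 others that also part 4 line codes gave at most 1. This argues against a chance split of the arrays but does not exclude it. The 100 splits cannot resolve a share below 1 in 100, and they moved repeat arrays of a line singly. Line SB alone is argued against as the carrier, since 928 targets passed without its arrays and 87.7% of them moved the same way in SB. Slide and culture form cannot be told apart: with slide as a fixed block the 20 named genes compared kept 0.674 of their median size (3.19 without and 2.15 with the block), past the 0.5 set beforehand, but with an interval over genes of 0.467 to 1.15 and only 2 spheres on the 2 slides that hold both forms. All 2525 targets kept 0.792 of their median size and 99.3% of them their direction, which excludes nothing, because they were chosen in a fit with the same arrays, and 7 of them still passed, with 2 others, as the median SE rose from 0.261 to 0.400. The culture form, in which serum and attachment changed together, stays open beside slide.

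Antigen presentation, macrophage and other leukocyte genes were far higher in tissue than in monolayers. Only the real split, 1 of 100, reached the 12353 targets of this comparison. The highest other split gave 2517 and was among the 9 others that also part 4 codes. This argues against a chance split, with the same limits on what 100 splits can show. Scan day is argued against, since the median of 11 leukocyte and antigen presentation genes was 7.53 on the first scan day, which holds both groups, against 7.32 over all arrays, a ratio of 1.03. These were the genes tested in both fits from the lists of macrophages, T and NK cells, B and plasma cells, neutrophils and mast cells, and antigen presentation. RNA from macrophages in the tissue is a candidate source: 0 of the 5 macrophage genes were well above background in most monolayers, they varied together between tumours more than all random lists (mean correlation 0.634), and none of them belongs to another list used here. CD86, CD163, FCGR1A and CYBB were well above background on all 24 tissue arrays and on 0 monolayer arrays, and the labels name no sorting step that would remove such cells. Of the 6 sphere arrays, however, CYBB was well above background on 4, and CD86, CD163 and FCGR1A on 1 each. The 5th gene, FCER1G, was so on 0 sphere arrays. Detection of these genes was thus not confined to tissue. Expression of these genes by the tumour cells themselves, lost in culture, stays open and was not tested.

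Hepatocyte genes were high in the spleen tumours SAS and SJ and low in the liver tumour SAL. They were also low in the liver tumours AH (-1.72) and TCL (-2.40), so a low level is not particular to SAL. Whether the organ labels of SAS and SAL were exchanged cannot be told apart from true labels: of the 200 targets that best part the other spleen and liver tumours without following the hepatocyte genes, 55.5% or, with a looser limit, 69.5% differed in the direction an exchange needs. Carry-over between arrays cannot be told apart either. The differences of SJ from its neighbour JLI spread 1.07 times as widely as those from NP. The differences of SAS from NP spread 1.02 times as widely as those from JLI. NP was the liver tumour nearest to SAS in the order of arrays, but it lay on another slide. Without SAS and SAL the liver comparison still had 0 targets past the threshold by limma, with 2626 at an unadjusted p under 0.05 against 1168. Liver tissue within the sampled spleen tumours, or its absence from SAL, AH and TCL, may also give this pattern, and no biological explanation was tested.

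The comparisons of organs and breeds had 0 targets past the threshold by limma, a number that all 100 of 100 splits reach by construction, so these splits tell nothing about chance and cannot exclude it. The highest other split gave 1 target for heart against spleen, 426 for breed and 3609 for liver against spleen. The last number is many times the real count and points to a structure of the tumours: that split put NP, JLI, SAS and SJ, the 4 tumours with high hepatocyte genes, into the same group of 5.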

How the results depend on the processing

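Of the tests in this part, the 75th percentile over detected probes, the fits by scan day, the background of all targets, slide as a random block and the fits without SAS, SAL and SJ were chosen only after the results were seen.

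Of 417 values of named genes under other choices, 47 kept their direction but no longer passed the threshold. A further 4 changed sign where the gene passed in either fit. Changes of sign between values that passed in neither fit were not counted. ACTG1, at 0.43 in tissue with its brightest probe and at -1.05 to -0.09 with its other probes, was at -0.15 after quantile normalization and at -0.42 in the series matrix values, NKX2-1 at -0.19 with slide as a fixed block and RHAG at -0.015 in the series matrix values; the cause was not tested. Other normalizations, background corrections and probe choices left the sphere count at 2047 to 2582 and the tissue count at 11210 to 12387. Against the 2525 targets between spheres and monolayers, slide as a fixed block gave 9 (7 of them among the 2525), and no block by case left 1625. Slide as a random block, which took the place of the block by case, gave 751. Line as a replicate block over the 12 arrays of 4 lines gave 1549, and that block with the EFB sphere paired with the EFS monolayer 1109. Of the 6 sphere lists that could be tested with the replicate block the same 2 passed, so it changed no other call among them. Leaving out whole lines gave 928 to 2065 (993 without EFB, 1224 without JHE, 928 without SB), and leaving out single spheres 1230 to 3206 (1230 without EFB, 1331 without JHE, 1597 without SB2), with fewer arrays each time. Against the 12353 targets between tissue and monolayers, 26302 passed with no filter on dim probes and 6585 when each array had to be well above background, since 35907 and 9817 were tested in place of 17835. Slide as a fixed block left 8071 and case as a replicate block, with 9 arrays of 4 codes, 4409; the cause was not tested. The first scan day alone gave 9350 and Golden Retrievers alone 11658. The comparisons of organs and breeds kept 0 targets by limma under every choice (320 to 2768 at an unadjusted p under 0.05), except that liver against spleen without SAL gave 1; leaving out the other liver tumours gave 0. The response of SB against the other lines went from 0 to 27 without the filter and to 3 without JHE; the cause was not tested. For the lists, an estimated correlation left 0 of 2 between spheres and monolayers, 0 of 4 for tissue, 0 of 3 for heart and 0 of 1 for liver (the cause was not tested), and fry gave 6, 15, 0 and 0. With all targets as background liver against spleen had 2 lists and tissue 6, where progenitor markers and neutrophil and mast cell genes also passed. By Pearson's r, 2 of the 4 related programme pairs remained with median scores (those with adipogenesis scores were lost). In spleen tumours alone, where 11 tumours are left, 2 remained (endothelial with adipogenesis and macrophage with T and NK cell scores were lost). By Spearman's rho endothelial with T and NK cell scores was also lost there (permutation adjusted p = 0.0929). Of the 8 coherent lists 5 remained with organ means taken out. Dim probes limit the comparisons: where a gene was not well above background on any array of a group, only a bound on its fold is given.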

Other observations

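In this part the hepatocyte values by tumour, the targets they share and the values of PTGS1 and NPC1 were drawn up only after the results were seen, while the tests of a shared shift, of title codes and of the EFB labels were written before.

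Hepatocyte genes set 4 tumours apart. The mean level of APOH, a plasma protein, the protease inhibitor SERPINA1 and the cytochromes CYP2E1 and CYP3A12 was 8.52 in NP and 8.38 in JLI, both labelled liver, and 7.49 in SAS and 6.25 in SJ, both labelled spleen. The other 20 tumours lay between -3.69 and 0.59, including the liver tumours AH (-1.72), TCL (-2.40) and SAL (-2.94). CYP2E1 stood at 9.80 in NP, 8.24 in SAS and -6.29 in SAL. Over 355 targets that NP and JLI share at 4 or more log2 units above the median tumour, the median excess was 6.30 in NP, 6.27 in JLI, 4.76 in SAS and 4.36 in SJ, and between -1.14 and 1.26 in the others. All 4 were scanned on the second day, SJ and JLI on slide 10, SAS on slide 11 and NP on slide 12.

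Spheres differed from monolayers partly in the direction of tissue. ACKR3 and MX1 were higher in both spheres and tissue, and HMGA1, FGF5 and PGR were lower in both. Of 16267 targets tested in both comparisons, 625 were higher in both (1025 in spheres and 4110 in tissue, 259 expected of independent lists) and 1027 were lower in both (1418 and 6700, 584 expected), against 85 higher in spheres and lower in tissue and 54 the other way. The 2 comparisons share their monolayers, which alone gives a correlation of 0.449 in simulated unchanged groups, as much as the observed 0.445 over 20012 targets. The observed covariance was 0.617 against a simulated 0.0748. With the monolayer lines split into separate controls the correlation was 0.366 in the median of 100 splits (0.263 to 0.442) and the covariance 0.55, above 0 in all 100. A shift shared by spheres and tissue is therefore a candidate explanation, across genes that are not independent replicates. What it comes from was not tested.

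Title codes that share their first letters (such as SAS and SAL, or TCH and TCL) could mark tumours of the same dog, which the labels do not say. With levels taken relative to the organ mean, or to the mean of all tumours for JLU, the only lung tumour, the mean correlation of the 5 such tumour pairs was 0.07, against a median of -0.05 and a 95th percentile of 0.19 in 10000 random relabellings (one-sided permutation p = 0.203). Without JLU it was -0.02 over 3 pairs (p = 0.447). The test did not pass, and with 5 pairs it could miss a resemblance. It is not known whether such correlations detect a shared dog. Deviations from the group means of tissue and monolayer arrays with the same code (SH left out) correlated at only 0.002 on average. The pair SAS and SAL, which lie far apart in hepatocyte genes, had a correlation of -0.437, while the other pairs ran from 0.16 to 0.223.

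The EFB monolayer is labelled spleen, while the EFB sphere and the EFS monolayer are labelled brain. The deviations of the EFB sphere correlated at 0.435 with those of the EFS monolayer and at 0.320 with those of the EFB monolayer, a difference of 0.115 in favour of EFS. The sphere was thus nearer to the monolayer with its organ label than to the one with its code. The margin over the 0.1 set beforehand was narrow and rests on single arrays. The prediction written for exchanged organ labels was met, but it cannot decide that question. Exchanged title codes or arrays would give this result, while organ labels exchanged under correct codes would not. The deviations of the 2 monolayers correlated at 0.212, below the highest correlation of EFB with another monolayer (0.345) and of EFS (0.228), so they were not closest to each other. The 2 correlations of the EFB sphere were its highest among the 12 monolayers.

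With slide as a fixed block 9 targets passed between spheres and monolayers, among them PTGS1, a prostaglandin synthase (9.81 ± 0.91, adjusted p = 0.00322, against 4.03 and adjusted p = 0.0516 without the block), and NPC1, a cholesterol transporter (2.44 ± 0.36, adjusted p = 0.0396). The other 7 have no gene symbol. Both genes were picked out after their values were seen.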
